A study of Mus musculus with 13 samples.

How the data were processed

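Total RNA of SM1 tumours, isolated with the RNeasy Micro kit, was converted to biotin-labelled cDNA and measured on 13 Affymetrix GeneChip mouse arrays. The groups were tumours of control recipients given vehicle (2 arrays) or dabrafenib and trametinib together (2), and of pmel-1 recipients given vehicle (2), dabrafenib (2), trametinib (2) or both (3). The labels do not state whether replicates come from separate animals, and no doses, times or batches are given in the sources used here. The values deposited by the authors are log2 intensities per probe set, which their processing notes ascribe to RMA and the affy package, without versions. The unit was checked on the values: array maxima run from 14.94 to 15.06 and the largest gap between arrays at the same quantile is 0.33. The probe set definition and any filter before deposition are not given in the sources used here. The number of arrays limits the precision.

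Of 45101 probe sets 64 are array controls, 34945 have exactly 1 gene symbol in the probe table, 932 have several and 9160 none. For each of 18193 symbols the probe set with the highest mean over all arrays was kept. Genes above the 40th percentile of all values (5.79) in at least 2 arrays were tested, 13783 in all. Symbols were checked against the gene names of the mouse reference annotation (GRCm38.p6), with 0 updated. Changes against a group that reads under 5.79 on every array are given with their SE but without a fold. Other probe sets were compared only for the passing genes with the largest changes, and where one went the opposite way the text says so. Genes named only from a list or for a small p were not checked in this way.

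Group means were fitted per gene over all 13 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with 7 residual degrees of freedom), so that all groups share 1 variance per gene. The 12 contrasts were the combination against vehicle (over both kinds of recipient and within each), pmel-1 against control recipients (over both arms and within each), the interaction of the transfer and the combination, dabrafenib and trametinib each against vehicle, and the 3 drug treatments against each other in pmel-1 recipients. P-values were adjusted by Benjamini-Hochberg within each contrast, and genes with an adjusted p under 0.05 are said to rise, fall or change. The fit was tested on simulated data with 200 changed genes of 13783 per comparison. At 2-fold it recovered 100.0% of changed genes for the combination over both kinds of recipient, 97.0% for the transfer over both arms, 59.7% for the interaction and between 85.1% and 95.5% for the others. False calls were 1.7% to 6.4%. The simulated noise was normal and independent between genes, with variances taken from the same fit. These rates need not hold for the arrays, where genes are not independent and RNA quality differed between groups.

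Gene lists numbered 25: MAPK output, melanocyte differentiation, MHC class I and antigen processing, MHC class II, T cell, cytotoxic effector and NK, interferon gamma response, type I interferon response, immune checkpoint, regulatory T cell, macrophage, suppressive macrophage, neutrophil and myeloid suppressor, dendritic cell, B cell, proliferation, fibroblast and matrix, endothelial, keratinocyte, skeletal muscle, adipocyte, erythroid, hypoxia and glycolysis, apoptosis regulators and receptor tyrosine kinases. Each was tested in each contrast with camera at its preset correlation of 0.01, adjusted over the 25 lists within a contrast. Camera was repeated with an estimated correlation, and fry, which asks whether the genes of a list move on balance in one direction without comparing them with other genes, was run beside it. Of the 300 tests camera passed 109, of which 0 passed with an estimated correlation and 77 with fry. It passed 9 lists for the combination over both kinds of recipient, 11 in pmel-1 and 6 in control recipients, and 13 for the transfer over both arms, 12 among vehicle and 11 among combination tumours. It passed 6 for the interaction, 11 for dabrafenib, 6 for trametinib, 10 for dabrafenib against trametinib and 5 and 9 for the combination against each. Lists of 13 general leukocyte and 11 housekeeping genes were tested in the same way beside 10 gene families, with p-values adjusted over these 12. Anchor genes not among the genes tested include Isg15, Foxp3, S100a8, Krt14 and Hba-a1.

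The lists, contrasts, filter, thresholds and most alternatives were chosen before the data were examined. Genes named in the report follow a rule fixed then. For each contrast it takes up to 10 rises and 10 falls with the largest change among genes that passed and whose 2 sides do not overlap, a criterion that the interaction, with its 4 groups, cannot use. Where fewer than 10 genes pass it takes the 10 with the smallest p. From each list it takes the anchor and up to 4 members with the smallest p. Symbols of the RIKEN, Gm and LOC kinds were counted but not named, and of the genes the rule gives not all are named.

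Similarity of drug effects was measured across genes, beside 100 simulations of unchanged groups that share the same vehicle arrays. The effects against 1 vehicle array each were added after the data were seen. RNA quality was read from the 3′ and 5′ control probe sets of Gapdh and Actb as the mean log2 ratio of 3′ over 5′ signal, and compared between groups with two-sided exact permutation tests. Alternatives were array weights, only the arrays compared, median centring, quantile normalization, no filter, a filter at the 60th percentile, the mean of a gene's probe sets, a replicate block, each array left out in turn, a 2-fold minimum, an adjusted p under 0.10 and eBayes with trend and robust settings. A covariate for the 3′ over 5′ ratio and the omission of the 4 arrays high in adipose or muscle genes were added after the data were seen.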

Results

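RNA from SM1 tumours was measured on 13 arrays. SM1 is a transplantable mouse melanoma that carries the BRAF V600E mutation, and the tumours grew in C57BL/6 mice that received splenocytes by adoptive transfer. The transferred cells came from pmel-1 mice, whose T cells carry a receptor for the melanocyte protein gp100 (the product of Pmel), or from C57BL/6 mice as a control. The pmel-1 recipients were given vehicle (2 arrays), the BRAF inhibitor dabrafenib (2 arrays), the MEK inhibitor trametinib (2 arrays) or both drugs (3 arrays), and the control recipients vehicle (2 arrays) or both drugs (2 arrays). The series concerns immunotherapy joined to BRAF and MEK inhibition, so the comparisons ask what each drug and each transfer did to tumour and immune genes. Values are log2 intensities whose quantiles differ by at most 0.33 between arrays, and 13783 genes were tested with limma. Log2 fold changes are given ± SE from that fit, and the number of arrays limits their precision. Detection calls were not used here, and an array that reads a gene under 5.79, the level of the filter, is taken as not well above background for it. Of the 285 values of named genes 62 have a group whose arrays all read under that level, among them those of Cxcl9, Iigp1, Kcnj13, Cd3g, Klrd1, Gzma and Ms4a4b, so the sizes of those 62 values are not exact and no fold is given for them. The replicates are not stated to come from separate animals, so p-values measure the spread between these samples.

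Across the genes tested, arrays of the same group correlated at r from 0.983 to 0.994 (8 pairs) and arrays of different groups at r from 0.905 to 0.994 (70 pairs). These values run across genes, which are not independent replicates. The first 3 principal components held 68.5%, 9.4% and 6.2% of the variance. RNA measures moved with the groups. The mean 3′ over 5′ log2 ratio of the array control probe sets was 1.08 ± 0.38 (SD, n = 7) in the pmel-1 tumours given a drug and 0.26 ± 0.09 (SD, n = 6) in the other tumours. The difference was 0.83 (two-sided exact permutation p = 0.0017, the smallest possible being 0.0006). Adipoq, an adipocyte hormone, read 10.05, 10.32 and 9.30 in pmel-1 combination replicate 2, dabrafenib replicate 2 and trametinib replicate 1, 7.54 in combination replicate 3 and from 4.75 to 5.97 elsewhere. Acta1, the actin of skeletal muscle, read 9.90 in control vehicle replicate 3 and from 5.51 to 6.61 elsewhere.

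**Figure D1:**
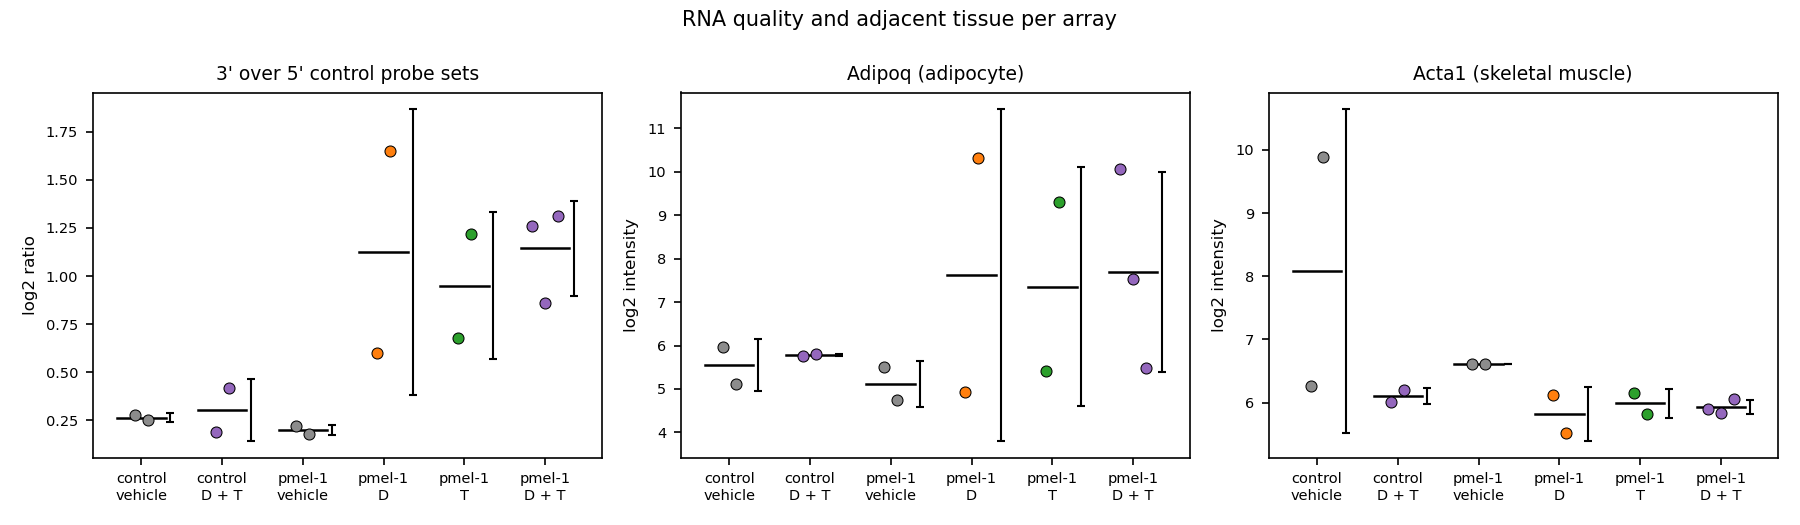
The 3′ over 5′ log2 ratio and the log2 intensities of Adipoq and Acta1 on each array, with points for arrays, black lines for group means and bars for ± SD. The pmel-1 tumours given a drug have ratios from 0.60 to 1.65 and the other tumours from 0.18 to 0.42.

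The combination was first compared with vehicle over both kinds of recipient (5 arrays against 4). Kcnj13, a potassium channel of pigment cells, rose by 4.69 ± 0.18 (adjusted p = 2.46e-08). Genes of melanosomes and pigment cells rose with it, Trpm1 by 3.80 ± 0.20 and Gpr143 by 3.80 ± 0.20, as did the interferon-induced genes Rtp4 (4.02 ± 0.17) and Irgm2 (3.39 ± 0.22). Other large rises were those of Tmem140 (3.92 ± 0.23), Astn1 (3.90 ± 0.10), Hhatl (3.63 ± 0.09), the semaphorin Sema6d (3.43 ± 0.10) and the lipase gene Mgll (4.03 ± 0.23), of which another probe set went the opposite way. Hmga2, a chromatin protein gene, changed by −4.93 ± 0.24 (adjusted p = 9.97e-08). The ETS factor gene Etv4, which ERK signalling induces, changed by −3.29 ± 0.08 (adjusted p = 1.86e-09). The homeobox gene Hoxa11 (−4.14 ± 0.15), the ligand gene Dhh (−3.87 ± 0.19), Csn3 (−4.04 ± 0.46), Hapln1 (−3.80 ± 0.39), Pth2r (−3.50 ± 0.41), Fam184b (−3.47 ± 0.30), Myrfl (−3.39 ± 0.13) and the integrin Itga8 (−3.35 ± 0.17) also fell. In all, 7252 of 13783 genes changed (52.6%), 3875 up and 3377 down, and 1253 of them by at least 2-fold.

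Genes that the MAPK pathway drives fell with the combination: of 17 MAPK output genes 11 fell and 1 rose (12 passed when adjusted over the list alone; median −0.80). Egr1, an immediate early transcription factor, changed by −2.42 ± 0.23, Ier3 by −1.09 ± 0.10, the cytokine gene Lif by −0.80 ± 0.09 and the ERK phosphatase gene Dusp6 by −0.76 ± 0.25 (adjusted p = 0.0251). Dusp6 no longer passed at −0.68, −0.69, −0.78 and −0.73 without control combination replicate 3, control vehicle replicate 1 and pmel-1 vehicle replicates 1 and 2, at −0.65 with a replicate block or at −0.37 with the 3′ over 5′ ratio as a covariate. Of 16 melanocyte differentiation genes 13 rose and 1 fell (14 adjusted over the list alone; median 0.82). Pmel, which encodes the antigen of the transferred T cells, rose by 1.45 ± 0.10 (adjusted p = 9.82e-07). The melanosome transport gene Rab27a rose by 2.33 ± 0.12 and the endothelin receptor Ednrb by 1.62 ± 0.09, while the receptor tyrosine kinase Kit changed by −2.09 ± 0.21. The list test (camera) gave adjusted p = 5.71e-04 and 5.10e-05, and adjusted p = 0.5443 for both with an estimated correlation.

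Over both kinds of recipient immune genes rose with the combination, while in control recipients alone the tests of interferon gamma response, MHC class I and MHC class II genes did not pass. Of 13 type I interferon response genes 13 rose (as many adjusted over the list alone; median 1.72). Among them were the RNA sensor Ddx58 (2.22 ± 0.12), the interferon feedback gene Usp18 (3.11 ± 0.22), Oas1a (1.82 ± 0.16) and Ifih1 (1.72 ± 0.16). Of 12 interferon gamma response genes 11 rose and 1 fell (12 adjusted over the list alone; median 1.62). The T cell chemokine Cxcl9 was at 2.11 ± 0.23 and the GTPases Igtp and Gbp3 at 2.59 ± 0.22 and 2.84 ± 0.26. Of 9 MHC class II genes 7 rose (7 adjusted over the list alone; median 1.44). H2-Aa (3.12 ± 0.27) and the invariant chain Cd74 (2.61 ± 0.25) led them, with H2-Eb1 at 2.04 ± 0.19. Of 14 MHC class I and antigen processing genes 11 rose and 1 fell (13 adjusted over the list alone; median 0.52). H2-K1 was at 0.71 ± 0.06 and the peptide loading gene Tapbp at 2.05 ± 0.14. The macrophage list had 11 of 14 genes up (11 adjusted over the list alone; median 1.07). These include the growth factor receptor Csf1r (1.55 ± 0.21) and the complement gene C1qc (1.18 ± 0.15). General leukocyte genes rose as well, 12 of 13 up (median 0.93, camera adjusted p = 8.32e-05, and adjusted p = 0.2991 with an estimated correlation). The 5 camera tests gave adjusted p = 1.51e-06, 6.54e-04, 0.0033, 0.0068 and 0.0012, and adjusted p = 0.5443 for each with an estimated correlation.

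Fewer of the T cell markers rose, a difference between lists that was not tested. Cd3g, a chain of the T cell receptor complex, rose by 1.06 ± 0.19, one of 3 T cell genes of 9 to pass (3 adjusted over the list alone; median 0.17). Cd8a was at 0.10 ± 0.07 (adjusted p = 0.2891). Of 10 cytotoxic and NK genes 4 rose (4 adjusted over the list alone; median 0.34), including the chemokine Ccl5 (1.66 ± 0.20) and the NK receptor Klrd1 (1.54 ± 0.24). The granzyme Gzmb stayed at 0.40 ± 0.21 (adjusted p = 0.1381). Cd3g, Klrd1 and Gzmb read under 5.79 on every array of both control groups and of pmel-1 vehicle tumours. Whether they changed in control recipients was therefore not measured. The PD-L1 gene Cd274 rose by 1.72 ± 0.19, one of 2 of 4 checkpoint genes. The regulatory T cell list had 1 gene up of 4, Ikzf2 (1.46 ± 0.15), and the dendritic cell list 1 up (Itgax, 0.80 ± 0.17) and 1 down of 7. The B cell list had 1 up of 5 (Cd22, 0.32 ± 0.08) and the neutrophil list 2 up of 4, Trem1 (0.47 ± 0.09) the lower p. In the B cell list the median was −0.04 and the mean 0.00. The suppressive macrophage list had 1 up and 3 down of 8, with the resistin-like gene Retnla at 1.25 ± 0.30 (0.85 and not passing with the 3′ over 5′ ratio as a covariate) and the vessel growth factor Vegfa at −1.18 ± 0.23. None of these 8 lists passed the camera test, their adjusted p lying between 0.0752 and 0.8817.

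Glucose uptake and oxygen response genes fell. Of 11 hypoxia and glycolysis genes 9 fell (9 adjusted over the list alone; median −1.13), the glucose transporter Slc2a1 by −1.80 ± 0.22, Egln3 by −2.71 ± 0.18 and Ankrd37 by −1.47 ± 0.19. Of 14 proliferation genes 8 fell and 1 rose (9 adjusted over the list alone; median −0.42). The replication genes Pcna, Mcm5 and Mcm2 changed by −1.08 ± 0.11, −1.25 ± 0.14 and −0.88 ± 0.09. The gene that rose was Mki67 (0.43 ± 0.12), at 0.35 and 0.36 and not passing without control vehicle replicate 1 or pmel-1 vehicle replicate 2, and at 0.24 and not passing with the 3′ over 5′ ratio as a covariate. The camera adjusted p was 0.0059 for hypoxia and 0.0099 for proliferation, and adjusted p = 0.5443 for both with an estimated correlation. Among apoptosis regulators 3 rose and 3 fell of 9 (8 adjusted over the list alone). The survival gene Bcl2l1 changed by −0.92 ± 0.10, Bcl2 by −0.52 ± 0.11 and the BH3-only killer gene Bmf by 1.17 ± 0.16. Of 11 receptor tyrosine kinases Met rose by 2.17 ± 0.12, Tyro3 rose by 1.15 ± 0.09 and Igf1r changed by −1.78 ± 0.17. Of the list 3 fell in all, with a median of 0.01 and a mean of −0.09.

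Of 13 fibroblast and matrix genes 6 rose, the small proteoglycans Lum by 2.16 ± 0.45 and Dcn by 1.92 ± 0.39 (median 0.46, camera adjusted p = 0.1648). Of 9 endothelial genes 3 rose, Vwf the most at 1.57 ± 0.20, and 1 fell. The erythroid list had 2 of 2 genes down (Alas2, −1.50 ± 0.35). By limma 0 of 4 keratinocyte, 0 of 6 skeletal muscle and 0 of 4 adipocyte genes passed, and 0, 2 and 0 had an unadjusted p under 0.05. Adipoq was at 1.40 ± 1.18. The adipocyte median was 0.12 and its test pointed down. The combination and vehicle tumours of pmel-1 recipients also differed in the 3′ over 5′ ratio. With that ratio as a covariate 76.6% of the 7252 calls were kept.

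**Figure D2:**
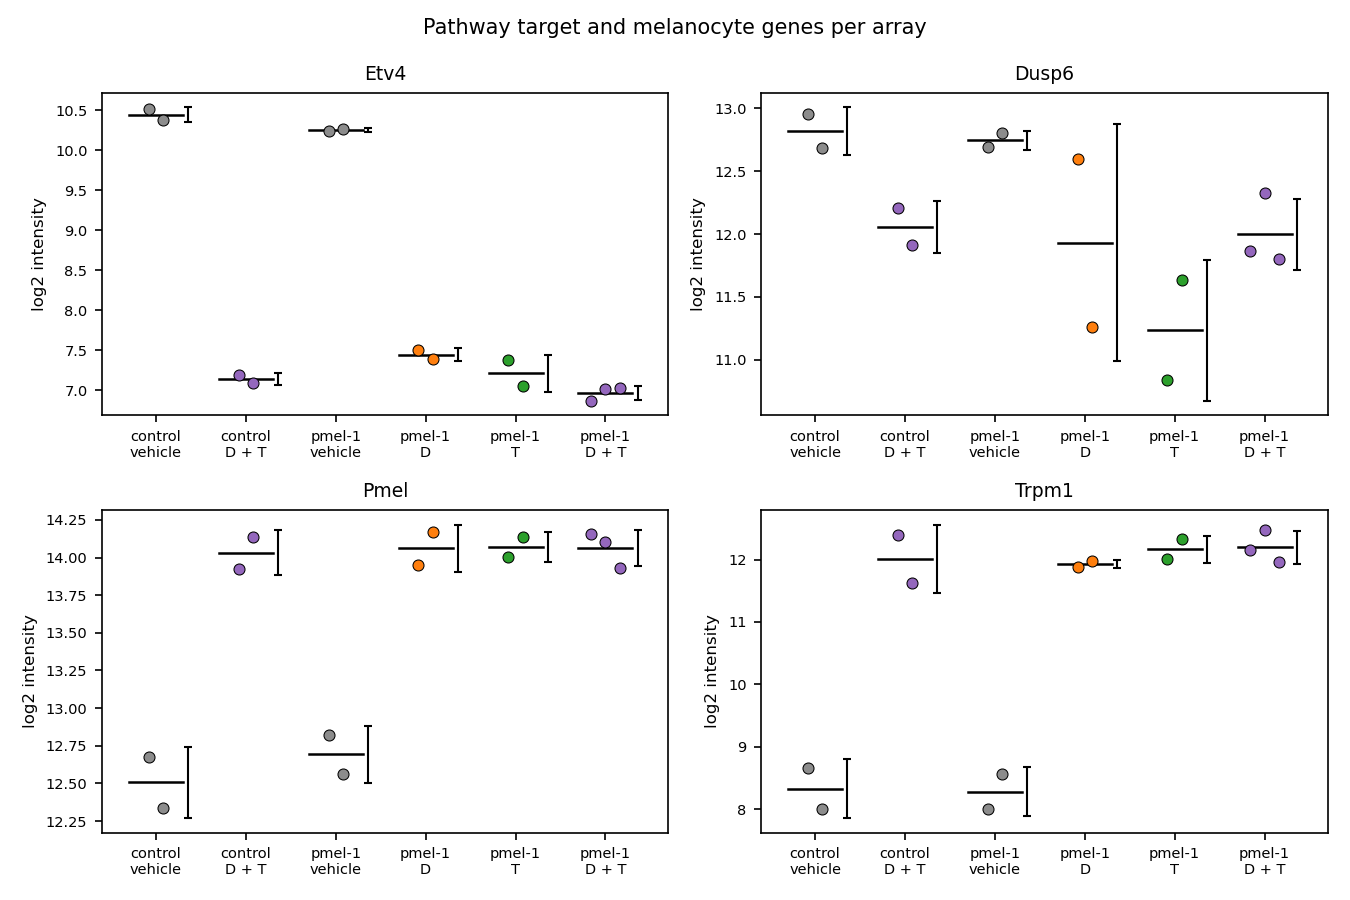
Log2 intensities of Etv4, Dusp6, Pmel and Trpm1 on each array, with points for arrays, black lines for group means and bars for ± SD. Etv4 averages 10.45 and 10.25 in the vehicle groups and from 6.97 to 7.44 in the groups given a drug.

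The combination was then compared with vehicle within each kind of recipient. In control recipients (2 arrays against 2) Kcnj13 rose by 4.51 ± 0.27, Astn1 by 4.04 ± 0.15, Pcolce2 by 4.0 ± 0.23, Tmem140 by 3.95 ± 0.35, Gpr143 by 3.89 ± 0.29, Trpm1 by 3.69 ± 0.29 and the adhesion gene Cdh1 by 3.63 ± 0.33. Hmga2 changed by −4.93 ± 0.35, Csn3 by −4.58 ± 0.68, Hoxa11 by −4.35 ± 0.22, Myrfl by −3.79 ± 0.19 and Etv4 by −3.30 ± 0.12. Cxcl9 and Ciita, the regulator of MHC class II, read under 5.79 on all 4 of these arrays, so whether they changed was not measured. Ddx58 (1.96 ± 0.17), Usp18 (2.10 ± 0.32), H2-Aa (2.12 ± 0.41) and Cd274 (1.30 ± 0.29) rose and the chemokine Cxcl11 changed by −0.83 ± 0.18. In all, 4874 genes changed, 2572 up and 2302 down. The camera test passed for 6 lists, among them type I interferon response (median 0.98, adjusted p = 4.40e-04), melanocyte differentiation (0.86, 1.00e-05) and MAPK output (−0.84, 0.0033), with adjusted p = 0.9701, 0.4464 and 0.9701 with an estimated correlation. It also passed for macrophage genes (8 of 14 up, median 0.91, adjusted p = 0.0091), proliferation (6 of 14 down, −0.40, 0.0091) and hypoxia and glycolysis (6 of 11 down, −1.25, 0.0119). These 3 had adjusted p = 0.9701 with an estimated correlation, and the last 2 no longer passed without control combination replicate 3 (−0.16) and control vehicle replicate 1 (−1.07). Lists that did not pass include interferon gamma response (3 up and 1 down of 12, median 0.45, adjusted p = 0.3379), MHC class II (3 up of 9, 0.66, 0.3799) and MHC class I (3 up and 1 down of 14, 0.006, 0.7448). Of the general leukocyte genes 5 of 13 rose (median 0.42, camera adjusted p = 0.0179, and 0.7080 with an estimated correlation).

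In pmel-1 recipients (3 arrays against 2) the genes that rose include the interferon genes Gbp6 (5.17 ± 0.47), Oasl2 (4.66 ± 0.40), Gbp2 (4.43 ± 0.44), Irgm2 (4.28 ± 0.30), Cxcl9 (4.19 ± 0.31), Igtp (4.14 ± 0.30) and Usp18 (4.13 ± 0.29), beside Kcnj13 (4.88 ± 0.25) and Rtp4 (4.54 ± 0.23). Hmga2 changed by −4.93 ± 0.32, Hapln1 by −4.19 ± 0.53, Hoxa11 by −3.92 ± 0.20, the cartilage collagen Col2a1 by −3.60 ± 0.40 and Etv4 by −3.28 ± 0.11. H2-Aa rose by 4.12 ± 0.37, Ciita by 0.91 ± 0.13, Cd3g by 2.21 ± 0.25, Klrd1 by 2.97 ± 0.33, the granzyme Gzma by 1.91 ± 0.21 and Csf1r by 1.97 ± 0.29. In all, 6282 genes changed, 3356 up and 2926 down, and 2756 with the 3′ over 5′ ratio as a covariate. The camera test passed for interferon gamma response (11 of 12 up, median 2.30, adjusted p = 5.27e-06), MHC class II (7 of 9, 1.85, 7.15e-05) and cytotoxic and NK genes (7 of 10, 0.86, 0.0044). With an estimated correlation these gave adjusted p = 0.3504, 0.3497 and 0.3497. Of the general leukocyte genes 11 of 13 rose (median 1.44, camera adjusted p = 4.24e-06, and 0.2879 with an estimated correlation). Across genes the effects of the combination in the pmel-1 and in the control recipients, which share 0 arrays, correlated at r = 0.82 (Spearman rho 0.78, covariance 0.347). Genes up in both numbered 1953 (626 if independent) and genes down in both 1808 (489 if independent), with 11 called in opposite directions.

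Whether the combination acted differently in the kinds of recipient was tested by the interaction (the pmel-1 effect minus the control effect, over 5 and 4 arrays). Cxcl9 was at 4.17 ± 0.45 (adjusted p = 0.0225), with all 4 control arrays under 5.79. Its mean was 4.30 ± 0.04 (SD, n = 2) in control vehicle and 4.32 ± 0.31 (SD, n = 2) in control combination tumours, and 6.07 ± 0.61 (SD, n = 2) in pmel-1 vehicle and 10.27 ± 0.44 (SD, n = 3) in pmel-1 combination tumours. Interferon-induced GTPases passed as well, Gbp6 at 3.99 ± 0.70, Igtp at 3.11 ± 0.44, Ifi47 at 2.93 ± 0.43 and Iigp1 at 2.84 ± 0.44. Genes of lymphocytes that passed were the T cell membrane gene Ms4a4b at 3.32 ± 0.49, Klrd1 at 2.85 ± 0.48, the T cell receptor segment Trbv1 at 2.79 ± 0.45 and Cd3g at 2.30 ± 0.37. The MHC class II gene H2-Eb1 was at 2.76 ± 0.38, the immunoproteasome gene Psmb8 at 1.94 ± 0.26 and the granzyme Gzma at 1.85 ± 0.32. Negative interactions were those of the connexin Gjc3 (−1.74 ± 0.23), Qpct (−1.68 ± 0.28), Zc3h6 (−1.60 ± 0.27), the protease inhibitor Serpinb1a (−1.50 ± 0.18), Ubl3 (−1.12 ± 0.18), the protease Ctsk (−1.02 ± 0.17) and Snapin (−1.0 ± 0.17), of which another probe set went the opposite way. In all, 39 genes passed, 32 with a positive and 7 with a negative interaction. This count was 0 without control combination replicate 2 or 3, control vehicle replicate 3 or pmel-1 vehicle replicate 1, and 5, 11, 19 and 25 without pmel-1 vehicle replicate 2, pmel-1 combination replicates 1 and 2 and control vehicle replicate 1. Each of the 19 passing genes named here lost its call in at least 1 of these omissions. The count was also 0 with the 3′ over 5′ ratio as a covariate, 90 with only the arrays compared, 65 with array weights, 10 after median centring and 1 with a replicate block.

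As lists, interferon gamma response genes had a median interaction of 2.06 (3 of 12 passed, 10 adjusted over the list alone; camera adjusted p = 1.25e-12). The median was 1.79 for MHC class II (3 of 9, 7 adjusted over the list alone; 1.25e-09) and 0.95 for MHC class I (4 of 14, 10 adjusted over the list alone; 3.10e-09). With an estimated correlation each of these had adjusted p = 0.1249. Type I interferon response genes had 1.56 (camera adjusted p = 2.19e-10, and adjusted p = 0.2349 with an estimated correlation). Cytotoxic and NK genes had 1.16 (adjusted p = 3.46e-06, and 0.1249 with an estimated correlation). T cell genes had 0.29 (1 of 9 passed; adjusted p = 0.0014, and 0.1249 with an estimated correlation), and no longer passed under the stricter filter (adjusted p = 0.0708). General leukocyte genes had a median of 0.89, with 2 of 13 passing (adjusted p = 2.45e-07, and 0.1912 with an estimated correlation). The macrophage median was 0.38 (adjusted p = 0.3055), that of MAPK output −0.28 (0.1912) and that of melanocyte differentiation −0.20 (0.1346). None of the 3 passed, nor did Pmel at −0.15 ± 0.20 or Dusp6 at 0.01 ± 0.50.

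**Figure D3:**
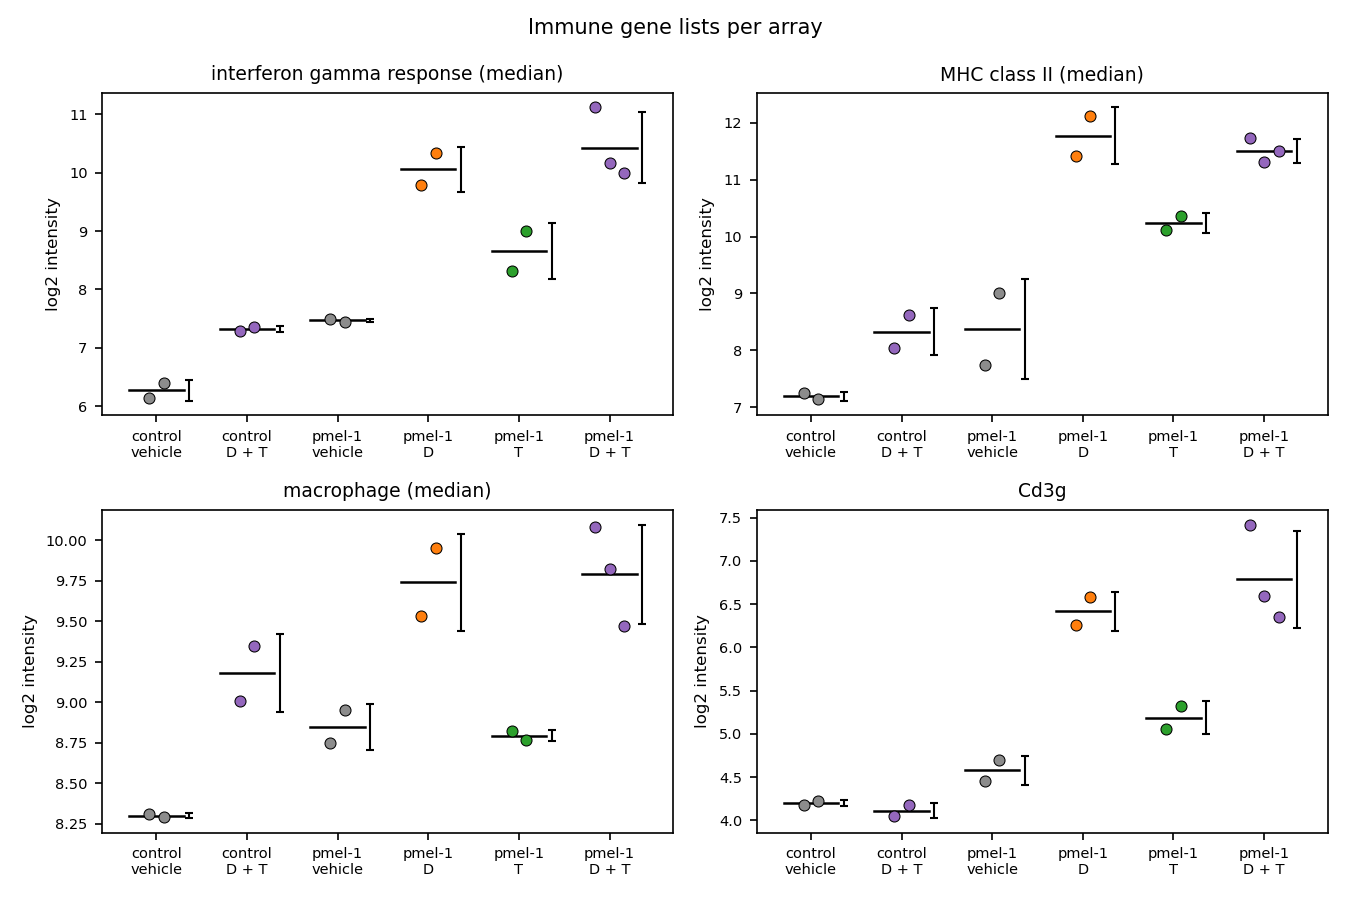
The median log2 intensity of the interferon gamma response, MHC class II and macrophage lists and the log2 intensity of Cd3g on each array, with points for arrays, black lines for group means and bars for ± SD. Interferon gamma medians lie from 6.15 to 7.49 in control recipients and pmel-1 vehicle tumours and from 8.32 to 11.12 in pmel-1 tumours given a drug.

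The effect of the transfer was taken over the vehicle and combination arms (5 pmel-1 against 4 control arrays). Interferon gamma targets rose in pmel-1 recipients, Iigp1 by 4.03 ± 0.22 (adjusted p = 1.55e-05), Cxcl9 by 3.86 ± 0.23 (adjusted p = 1.91e-05), Gbp2 by 3.74 ± 0.33 and Ifi47 by 1.86 ± 0.21. Other rises were those of the arginase Arg1 by 2.42 ± 0.31, the chitinase-like Chil3 by 2.07 ± 0.21, the lectin Clec10a by 1.92 ± 0.24 and the chemokine Ccl9 by 1.74 ± 0.24. The suppressive macrophage list had 3 of 8 genes up (median 0.26, camera adjusted p = 1.40e-04, and 0.0640 with an estimated correlation). Trbv1 rose by 2.40 ± 0.22, Cd3g by 1.53 ± 0.19, Cd3d by 0.94 ± 0.12, Klrd1 by 1.68 ± 0.24, the cytotoxic granule gene Nkg7 by 1.16 ± 0.16 and Ly6e by 1.78 ± 0.29. Cd8a was at 0.00 ± 0.07 and Gzmb at 0.59 ± 0.21, and neither passed (adjusted p = 0.9858 and 0.1441). The matrix gene Aspn changed by −1.63 ± 0.25 and the guanylate cyclase Gucy1a1 by −1.25 ± 0.23. Smaller falls were those of Btaf1 (−0.56 ± 0.11), Stk16 (−0.54 ± 0.10), Ints8 (−0.54 ± 0.11), Timm21 (−0.50 ± 0.11), Rasa1 (−0.48 ± 0.09) and Ank (−0.46 ± 0.10), and of Dnmt3a (−0.47 ± 0.10) and Cep192 (−0.45 ± 0.09), each with another probe set going the opposite way. The tumour genes Pmel (0.11 ± 0.10) and Dusp6 (−0.07 ± 0.25) did not pass.

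In all, 279 genes changed between recipients, 185 up and 94 down. Leaving out 1 array gave 61 without pmel-1 vehicle replicate 1, 75 without control vehicle replicate 3, 78 and 143 without control combination replicates 2 and 3, and 150, 127 and 446 without pmel-1 combination replicates 1, 2 and 3. Of the 26 passing genes named for this comparison 13 passed with each array left out in turn, and Ly6e, Msr1, Ndrg1 and the 10 that fell did not. With the 3′ over 5′ ratio as a covariate the count was 79, and 123 without the 4 arrays high in adipose or muscle genes. Interferon gamma response genes had 9 of 12 up (10 adjusted over the list alone; median 1.49; camera adjusted p = 3.65e-17) and MHC class II 7 of 9 (1.32; 9.02e-13). MHC class I had 7 of 14 (0.53; 5.51e-12) and cytotoxic and NK genes 4 of 10 (0.62; 1.99e-07). Each of these 4 had adjusted p = 0.0640 with an estimated correlation. Macrophage genes had 4 of 14 up (8 adjusted over the list alone; median 0.58; camera adjusted p = 1.99e-07, and 0.1287 with an estimated correlation), with the scavenger receptor Msr1 at 1.06 ± 0.15. Of 13 general leukocyte genes 10 rose (median 0.80, camera adjusted p = 4.17e-15, and 0.0464 with an estimated correlation). Of 11 hypoxia genes 1 rose, Ndrg1 (0.90 ± 0.19), and the list passed (median 0.43, camera adjusted p = 7.95e-05, and 0.2826 with an estimated correlation). By limma 0 of 13 fibroblast genes passed (median −0.60, 4 with an unadjusted p under 0.05). The camera test of that list passed (adjusted p = 8.42e-04, and 0.4308 with an estimated correlation), but not at −0.27 without control vehicle replicate 3. Proliferation (median −0.17, adjusted p = 0.0386) and endothelial genes (−0.23, 0.0473) passed with 0 genes each, had adjusted p = 0.4607 with an estimated correlation and each lost its call in 4 of the 9 omissions.

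Among vehicle tumours (2 arrays against 2) 0 genes passed by limma, the smallest adjusted p being 0.0671, and 1822 had an unadjusted p under 0.05. The smallest p were those of Iigp1 (2.61 ± 0.32, adjusted p = 0.0671), the carboxypeptidase Cpm (1.57 ± 0.21), the chaperone Hsph1 (−1.01 ± 0.14), Mfsd2a (−0.74 ± 0.10), Kbtbd8 (−1.18 ± 0.17), Chil3 (2.02 ± 0.31), Ccl6 (1.79 ± 0.28), F13a1 (1.18 ± 0.19) and Klf15 (0.82 ± 0.13). The count was 48 without control vehicle replicate 1 and 38 without pmel-1 vehicle replicate 2. The camera test passed for 12 lists, among them interferon gamma response genes (median 0.46, adjusted p = 9.46e-05) and the suppressive macrophage list (0.36, 4.43e-04), with adjusted p = 0.5304 and 0.1028 with an estimated correlation. General leukocyte genes had a median of 0.36 with 0 of 13 passing (camera adjusted p = 2.98e-05, and 0.3285 with an estimated correlation). Lists of other cell types also passed, fibroblast and matrix (−0.69, adjusted p = 0.0466), endothelial (−0.32, 0.0466), skeletal muscle (−0.65, 0.0253) and erythroid (0.90, 0.0259). With an estimated correlation these 4 had adjusted p = 0.7187, 0.7026, 0.6969 and 0.5304. Without control vehicle replicate 3, the array high in Acta1, none of the 4 passed, at 0.13, −0.19, 0.05 and 0.45.

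Among combination tumours (3 pmel-1 arrays against 2 control) 584 genes changed, 366 up and 218 down. Cxcl9 rose by 5.95 ± 0.31 (adjusted p = 7.51e-06), Gbp2 by 5.46 ± 0.44, Iigp1 by 5.45 ± 0.29, Gbp6 by 4.91 ± 0.47, Igtp by 4.34 ± 0.30. Further rises were those of Trbv1 by 3.80 ± 0.30, H2-Ab1 by 3.78 ± 0.28, Ms4a4b by 3.61 ± 0.33, H2-Aa by 3.55 ± 0.37 and Cd74 by 3.40 ± 0.34. Cd3g rose by 2.67 ± 0.25, Nkg7 by 2.10 ± 0.22, the immunoproteasome gene Psmb9 by 2.62 ± 0.21 and the peptide transporter Tap1 by 2.84 ± 0.26. Among the genes that fell were Aspn at −2.03 ± 0.33, the eosinophil chemokine Ccl11 at −1.93 ± 0.24, the lymphatic receptor Lyve1 at −1.88 ± 0.45, Enpep at −1.70 ± 0.42, Gucy1a1 at −1.64 ± 0.32, the fibrillin Fbn2 at −1.59 ± 0.40 and Igfbp7 at −1.36 ± 0.30. The myelin enzyme Ugt8a was at −1.75 ± 0.30 and Gsdme at −1.42 ± 0.27. Of 13 fibroblast and matrix genes 1 fell (median −0.44, camera adjusted p = 0.0064, and 0.5754 with an estimated correlation), a call lost at −0.41 without control combination replicate 3. Of 9 endothelial genes 0 passed, and the list did not (median −0.16, adjusted p = 0.2829). Interferon gamma response genes had 10 of 12 up (median 2.53; camera adjusted p = 1.38e-18), MHC class II 7 of 9 (2.22; 3.15e-14) and T cell genes 4 of 9 (0.23; 1.23e-04). Each had adjusted p = 0.0531 with an estimated correlation. General leukocyte genes rose in 11 of 13 cases (median 1.11, camera adjusted p = 3.02e-14, and 0.0581 with an estimated correlation). The count was 119 and 174 without control combination replicates 2 and 3, and 217, 181 and 1033 without pmel-1 combination replicates 1, 2 and 3. Of the 23 passing genes named here 15 passed with each array left out in turn, Ccl11 among them, and the other 8 genes that fell did not. Only 46 genes passed with the 3′ over 5′ ratio as a covariate, which averaged 1.15 ± 0.24 (SD, n = 3) against 0.30 ± 0.17 (SD, n = 2) (exact permutation p = 0.10, the smallest possible). There were 295 without the adipose and muscle arrays and 378 with only the arrays compared.

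Each drug alone was compared with vehicle in pmel-1 recipients (2 arrays against 2). With dabrafenib Mgll rose by 4.80 ± 0.33, Kcnj13 by 4.72 ± 0.27, Gbp6 by 4.66 ± 0.52, H2-Aa by 4.48 ± 0.41, Cd74 by 4.27 ± 0.38, Oasl2 by 4.22 ± 0.44, Rtp4 by 4.15 ± 0.25, Cxcl9 by 3.99 ± 0.34 and Irgm2 by 3.94 ± 0.32. Hmga2 changed by −4.48 ± 0.35, Hoxa11 by −3.70 ± 0.22, Lyve1 by −3.64 ± 0.50, the transcription regulator Id3 by −3.35 ± 0.26, Col2a1 by −3.47 ± 0.44 and Etv4 by −2.81 ± 0.12. Pmel rose by 1.37 ± 0.15, Klrd1 by 3.26 ± 0.36, Cd3g by 1.84 ± 0.27 and Csf1r by 2.26 ± 0.32, and Dusp6 was at −0.82 ± 0.37 (adjusted p = 0.1023). In all, 5709 genes changed, 3012 up and 2697 down. The count was 3643 without dabrafenib replicate 2, 2511 with the 3′ over 5′ ratio as a covariate and 3186 without the adipose and muscle arrays. The macrophage list had 10 of 14 genes up (median 1.42, camera adjusted p = 9.59e-04), MHC class II 7 of 9 (2.08, 2.05e-05) and interferon gamma response 10 of 12 (2.09, 2.05e-05). Each had adjusted p = 0.3753 with an estimated correlation. Of 13 general leukocyte genes 11 rose (median 1.40, camera adjusted p = 1.36e-06, and 0.2761 with an estimated correlation).

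With trametinib Kcnj13 rose by 5.48 ± 0.27 (44.7-fold), Trpm1 by 3.89 ± 0.29, Gpr143 by 3.87 ± 0.29, Hhatl by 3.86 ± 0.13, Astn1 by 3.59 ± 0.15, the granule gene Sytl2 by 3.35 ± 0.18 and the connexin Gjb6 by 3.33 ± 0.15. Hmga2 changed by −4.74 ± 0.35, the ETS factors Etv5 and Etv4 by −4.62 ± 1.10 and −3.04 ± 0.12, the cyclin Ccnd1 by −2.92 ± 0.41, Egr1 by −2.89 ± 0.34 and Dusp6 by −1.51 ± 0.37 (adjusted p = 0.0077). Pmel rose by 1.38 ± 0.15 and the kinases Cdk1 and Aurkb of dividing cells changed by −1.34 ± 0.13 and −1.86 ± 0.22. Cd3g (0.61 ± 0.27, adjusted p = 0.1022) and Csf1r (0.80 ± 0.32, adjusted p = 0.0664) did not pass, and the mannose receptor Mrc1 changed by −1.05 ± 0.32. Dusp6 no longer passed at −1.12 without trametinib replicate 2 or at −0.93 with the 3′ over 5′ ratio as a covariate, Etv5 at −2.25 with that covariate, and Mrc1 at −0.84 without trametinib replicate 2 or pmel-1 vehicle replicate 2. In all, 5323 genes changed, 2693 up and 2630 down, and 3371 with the 3′ over 5′ ratio as a covariate. Of 14 proliferation genes 11 fell (median −0.85, camera adjusted p = 1.97e-05) and of 17 MAPK output genes 11 (−1.38, 2.79e-05). Both had adjusted p = 0.7301 with an estimated correlation. The interferon gamma response median of 0.99 (adjusted p = 0.0255, and 0.7301 with an estimated correlation) no longer passed at 0.80 without trametinib replicate 1 or at 0.58 with the ratio as a covariate. The general leukocyte list did not pass (4 of 13 genes up, median 0.36, adjusted p = 0.1408). Across genes the dabrafenib and trametinib effects correlated at r = 0.91 (rho 0.90, covariance 0.377) against r = 0.50 and covariance 0.0154 in 100 simulations of unchanged groups that share the vehicle arrays. They shared 2236 genes up (589 if independent) and 2144 down (515 if independent), with 3 in opposite directions. The counts if independent do not allow for the shared vehicle arrays, which can make calls agree.

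Dabrafenib and trametinib tumours were compared directly (2 arrays against 2). Genes higher with dabrafenib were Adgb (2.58 ± 0.24, adjusted p = 0.0047), Ms4a4b (2.58 ± 0.36), Cd74 (2.35 ± 0.38), H2-Eb1 (2.27 ± 0.28), Iigp1 (2.26 ± 0.32), Klrd1 (2.23 ± 0.36), Calhm6 (2.06 ± 0.30), Cxcl9 (2.02 ± 0.34) and the fungal lectin receptor Clec7a (1.97 ± 0.20). Others were C1qc (1.39 ± 0.23), the lysozyme Lyz2 (1.58 ± 0.30), the Fc receptor Fcgr1 (1.16 ± 0.22) and Ciita (0.79 ± 0.14). Genes lower with dabrafenib were the heat shock genes Hspa1a (−2.86 ± 0.51) and Hspa1b (−2.55 ± 0.47), the endothelial claudin Cldn5 (−1.66 ± 0.27), the collagen enzyme P4ha2 (−1.26 ± 0.20), Ptp4a3 (−1.15 ± 0.17), Sdc1 (−1.13 ± 0.20), Ets2 (−1.06 ± 0.15) and Adgrf5 (−1.03 ± 0.18). Csf1r (1.45 ± 0.32), Cd3g (1.23 ± 0.27) and Dusp6 (0.69 ± 0.37) did not pass (adjusted p = 0.0665, 0.0731 and 0.5155). In all, 107 genes differed, 81 up and 26 down. The count was 0 without trametinib replicate 2, 8 without dabrafenib replicate 2, 23 without trametinib replicate 1 and 283 without dabrafenib replicate 1. None of the 21 passing genes named here kept its call in every omission. It was 0 with only the arrays compared, 17 without the adipose and muscle arrays, 161 after quantile normalization and 191 with the 3′ over 5′ ratio as a covariate. That ratio averaged 1.13 with dabrafenib and 0.95 with trametinib (exact permutation p = 1.0, the smallest possible being 0.1667).

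The macrophage list was higher with dabrafenib in 3 of 14 genes (8 adjusted over the list alone; median 1.07; camera adjusted p = 1.07e-09) and MHC class II in 6 of 9 (7 adjusted over the list alone; 1.82; 5.25e-11). Cytotoxic and NK genes were higher in 2 of 10 (6 adjusted over the list alone; 0.85; 9.78e-07). All 3 had adjusted p = 0.1199 with an estimated correlation. Interferon gamma response genes had a median of 1.17 (adjusted p = 1.82e-11) and hypoxia and glycolysis genes one of −0.86 (1.05e-09). Both had adjusted p = 0.1389 with an estimated correlation. T cell genes had 0.18 (adjusted p = 0.0075, and 0.1389 with an estimated correlation), which no longer passed at 0.068 without the adipose and muscle arrays, at 0.14 without trametinib replicate 1 or under the stricter filter (adjusted p = 0.1924). Endothelial genes were lower with dabrafenib (−0.56, adjusted p = 0.0017, and 0.3882 with an estimated correlation), but the list did not pass at −0.31 without dabrafenib replicate 1. Proliferation genes had 0.28 (adjusted p = 1.41e-04, and 0.3632 with an estimated correlation), and did not pass at 0.14 without the adipose and muscle arrays. The general leukocyte median was 1.12, with 7 of 13 genes passing (camera adjusted p = 3.36e-17, and 0.0398 with an estimated correlation). Macrophage medians per array were 9.53 and 9.95 with dabrafenib and 8.82 and 8.77 with trametinib.

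The combination was set against each drug in pmel-1 recipients (3 arrays against 2). Against trametinib, Gbp6 rose by 2.61 ± 0.47, Iigp1 by 2.44 ± 0.29 (adjusted p = 0.0085), Gbp2 by 2.37 ± 0.44, Cxcl9 by 2.22 ± 0.31, Ms4a4b by 2.20 ± 0.33, Igtp by 2.02 ± 0.30. H2-Eb1 rose by 2.0 ± 0.26, Klrd1 by 1.94 ± 0.33, Gbp3 by 1.91 ± 0.35, Adgb by 1.90 ± 0.22 and Cd3g by 1.60 ± 0.25. Wfdc3 changed by −1.77 ± 0.32, Cldn5 by −1.53 ± 0.25, the stress factor Atf3 by −1.22 ± 0.22, Ptp4a3 by −1.06 ± 0.16, Sdc1 by −1.01 ± 0.18 and P4ha2 by −1.01 ± 0.19. In all, 151 genes changed, 118 up and 33 down. The count was 0, 28, 42 and 63 without trametinib replicates 2 and 1 and combination replicates 2 and 1, and 286 with array weights. None of the 17 passing genes named here kept its call without trametinib replicate 2. Interferon gamma response genes had a median of 1.54 (6 of 12 passed, 12 adjusted over the list alone; camera adjusted p = 7.15e-17) and macrophage genes one of 1.03 (3 of 14, 11 adjusted over the list alone; 3.65e-10). Both had adjusted p = 0.0880 with an estimated correlation. General leukocyte genes had a median of 1.15, with 10 of 13 up (camera adjusted p = 2.12e-17, and 0.0404 with an estimated correlation).

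Against dabrafenib 0 genes passed by limma, every adjusted p being 1.0, and 246 had an unadjusted p under 0.05. The smallest p were those of the carbonyl reductase Cbr2 (0.82 ± 0.15), Pramel12 (0.44 ± 0.10), F13a1 (0.74 ± 0.17), Etv4 (−0.47 ± 0.11), Mybl2 (0.59 ± 0.14), Gja4 (0.75 ± 0.18), Gpd1 (−0.50 ± 0.12), Tsacc (−0.46 ± 0.12), Atad5 (0.43 ± 0.11) and Btc (0.36 ± 0.10). Cxcl9 was at 0.20 ± 0.31, Pmel at 0.00 ± 0.14 and Csf1r at −0.28 ± 0.29. Camera passed 5 lists at its preset correlation, but none with an estimated one. They were MAPK output, interferon gamma response, type I interferon response, proliferation and endothelial genes. With 1 array left out the MAPK output median ran from −0.53 to 0.30. Type I interferon response genes had a median of 0.44 (camera adjusted p = 6.87e-09, and 0.7182 with an estimated correlation), which no longer passed at 0.25 without dabrafenib replicate 1. Across genes the effect of the combination correlated with that of dabrafenib at r = 0.98 (rho 0.97, covariance 0.445) and with that of trametinib at r = 0.92 (rho 0.91, covariance 0.387). Each stood against r = 0.55 in simulations of unchanged groups with covariances of 0.0153 and 0.0154. Genes up in both numbered 2848 (733 if independent) for dabrafenib and 2393 (656) for trametinib. Genes down in both numbered 2507 (573) and 2286 (558), with 0 and 1 in opposite directions. Here too the counts if independent do not allow for the shared vehicle arrays. With each effect taken against its own 1 of the 2 vehicle arrays, and 0 arrays shared, r was 0.93 and 0.92 for the combination and dabrafenib (covariance 0.434 and 0.431), 0.86 and 0.87 for the combination and trametinib (0.373 and 0.376) and 0.84 and 0.87 for dabrafenib and trametinib (0.361 and 0.368).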

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

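The 2 tests of normalization and the exchange of arrays within each drug arm were chosen only after the result was seen, as were the refits with the 3′ over 5′ ratio as a covariate. The other tests were planned. List medians below are taken over genes, while the SE given with one is from a fit to the list's median on each array.

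The effect of the combination differed between pmel-1 and control recipients by the interaction test in 39 genes. The median interaction was 2.06 for the interferon gamma response list and 1.79 for the MHC class II list, and that of Cxcl9, which reads under 5.79 on all control arrays, was 4.17. By the direct contrast 107 genes differed between dabrafenib and trametinib tumours, and the macrophage list differed by a median of 1.07. Outside the genes tested, the 3′ over 5′ log2 ratio was 0.83 higher in the 7 pmel-1 tumours given a drug than in the other 6. Of the probe sets with several symbols or none, 4588 read above 5.79 in at least 2 arrays. Of these 1527 passed between combination and vehicle tumours, 1028 up and 499 down (33.3%).

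For the interferon gamma interaction (median 2.06, SE 0.55) the tables argue against 3 technical or compositional causes, each only in the form stated. Against a shift that between-array normalization gives to genes of like intensity, the median lay above 100% of 10000 random lists of matched expression. Such lists are not co-regulated, so they speak to no other cause. The list had already passed camera against the other genes, so only the matching on expression is new here. Median centring took the count of 39 genes to 10 and quantile normalization to 43. These moved the median interaction of all genes by −0.034 and 0.023. The lowest median with 1 array left out was 1.75, without pmel-1 combination replicate 2. It was above the 1.03 that a single deviating array would need to reach. The largest SE over the omissions was 0.67. An equal rise of all leukocytes would move general leukocyte genes as much, and their median interaction over 13 genes was 0.89 (SD 0.68), below 2.06. That list cannot exclude an influx of some kinds of leukocyte. Ms4a4b, Klrd1, Trbv1 and Cd3g had interactions above 2.06, while the T cell list as a whole had a lower median. RNA quality stays open: with the 3′ over 5′ ratio as a covariate the median was 1.62 (SE 0.60) while the 39 calls fell to 0, their median size going from 1.94 to 1.49 and their median SE from 0.32 to 0.31, and a response of the tumours to the pmel-1 cells may be as much the source.

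More than 50% of the genes tested changed between combination and vehicle tumours, 7252 in all. Chance was tested with 100 drawn splits of the 9 arrays into 5 and 4. Only 1, the real one, gave as many calls in a 2-group fit (6545), which argues against chance for these samples. The highest other (5202) differs from the real split only in the side of control combination replicate 2, so it is not an unrelated grouping. The replicates are not stated to come from separate animals. RNA quality as the whole cause is argued against by 76.6% of the calls being kept with the covariate and by the control recipients. Their ratios overlap (0.19 and 0.42 with the combination, 0.28 and 0.25 with vehicle), and 4861 of their 4874 calls were kept. In pmel-1 recipients the ratios do not overlap (0.86 to 1.31 against 0.18 and 0.22), and 2652 of 6282 calls were kept. There RNA quality and drug cannot be told apart. A further between-array normalization changed the count little, and quantile normalization kept 7019 of the 7252 calls. The deposited values already had quantiles within 0.33 of each other, so few calls could be lost to it. It cannot tell whether the normalization before deposition shaped this count. Median centring, which took the interaction from 39 genes to 10, kept 6939 (95.7%). The planned test on 11 housekeeping genes decides nothing (median −0.16, SD 0.52). An effect of the drugs on the tumour cells is a hypothesis that stays open for this count, which was found and tested on the same data. The MAPK output and melanocyte differentiation lists were fixed before the data were examined. Both passed the camera test in control recipients at its preset correlation, but not with an estimated one.

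For pmel-1 against control recipients chance cannot be excluded by such splits, as 5 of 100 gave at least the real count of 4, and the highest other gave 6545. That highest one follows the drug, which points to a structure of the samples; with the drug in the fit and arrays exchanged within each arm, 1 of 60 exchanges, the real one, gave 32 calls and the others at most 0.

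The macrophage list was lower with trametinib than with dabrafenib by a median of 1.07. General leukocyte genes differed by 1.12 (SD 0.55), so fewer leukocytes in trametinib tumours may explain it. Macrophages express general leukocyte genes too, so this test cannot tell fewer leukocytes of all kinds from fewer macrophages. The T cell list differed by less. RNA quality is argued against, as the median was 0.93 (SE 0.23) with the covariate. A single deviating array stays open: without dabrafenib replicate 2 the median was 0.59, near 0.54, the level at which 1 array would account for it. The largest SE over the omissions was 0.30. Whether trametinib acts on these cells was not tested.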

How the results depend on the processing

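The 3′ over 5′ covariate and the omission of the adipose and muscle arrays were chosen only after the data were seen, and the other alternatives were planned. The combination against vehicle over both kinds of recipient passed in 7252 genes and from 6267 to 7276 with 1 array left out, and only a 2-fold minimum moved it by more than 1.5 times, to 1253. For no count, list or gene that changed below was the cause tested, except that a 2-fold minimum or another threshold changes a count by construction, and leaving out 1 of 2 arrays leaves a lone array that is assumed to vary like the other groups.

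With 1 array left out, pmel-1 against control recipients gave 61 to 446 genes against 279, the interaction 0 to 33 against 39, the combination 4506 to 5943 in pmel-1 and 3265 to 3939 in control recipients, dabrafenib 3643 to 5689, trametinib 3644 to 4110. The transfer among vehicle tumours gave 0 to 48 against 0 and among combination tumours 119 to 1033 against 584, dabrafenib against trametinib 0 to 283 against 107. The combination gave 0 against dabrafenib in every omission and 0 to 102 against trametinib, where all arrays gave 0 and 151.

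With a 2-fold minimum the counts were 78 for pmel-1 against control recipients, 1521 and 1231 for the combination in pmel-1 and control recipients, 1458 for dabrafenib, 1285 for trametinib, 216 for the transfer among combination tumours, 68 for dabrafenib against trametinib and 79 for the combination against trametinib. At an adjusted p under 0.10 they were 959 for pmel-1 against control recipients, 121 for the interaction, 17 and 1632 for the transfer among vehicle and combination tumours, 229 for dabrafenib against trametinib and 355 for the combination against trametinib. With a replicate block they were 65 for pmel-1 against control recipients, 1 for the interaction, 232 for the transfer among combination tumours, 24 for dabrafenib against trametinib and 12 for the combination against trametinib.

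With the 3′ over 5′ covariate the counts were 79 for pmel-1 against control recipients, 0 for the interaction, 2756 for the combination in pmel-1 recipients, 2511 for dabrafenib, 3371 for trametinib, 2 and 46 for the transfer among vehicle and combination tumours and 191 for dabrafenib against trametinib. Without the adipose and muscle arrays they were 123 for pmel-1 against control recipients, 3186 for dabrafenib, 1 and 295 for the transfer among vehicle and combination tumours and 17 for dabrafenib against trametinib.

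With only the arrays compared the interaction gave 90 genes, the transfer 2 among vehicle and 378 among combination tumours, and dabrafenib against trametinib 0. Array weights gave 65 for the interaction, 5 for the transfer among vehicle tumours and 286 for the combination against trametinib. Median centring gave 10 for the interaction. Quantile normalization gave 1 for the transfer among vehicle tumours and 161 for dabrafenib against trametinib, and no filter gave 3 for the transfer among vehicle tumours. A stricter filter, the mean of probe sets and the trend and robust settings kept every count within 1.5 times.

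Median list changes that reversed were as follows, where a change of sign counts only if the list passed in the main or the altered fit. With the 3′ over 5′ covariate the adipocyte interaction was −1.54, and in the transfer among combination tumours apoptosis regulators were at 0.19, MAPK output at 0.13 and immune checkpoint at −0.048. Quantile normalization gave 0.032 for apoptosis regulators there. Without the adipose and muscle arrays, in the transfer among vehicle tumours, fibroblast genes were at 0.13 and skeletal muscle at 0.05, and immune checkpoint was at 0.33 between combination and dabrafenib. With 1 array left out, fibroblast genes ran from −1.20 to 0.13 and skeletal muscle from −1.25 to 0.05 in the transfer among vehicle tumours. Fibroblast genes ran from −0.82 to 0.58 and adipocyte genes from −1.79 to 1.29 between dabrafenib and trametinib. Between combination and dabrafenib MAPK output ran from −0.53 to 0.30, interferon gamma response from −0.038 to 0.57, fibroblast genes from −0.50 to 0.83, immune checkpoint from −0.42 to 0.37 and hypoxia and glycolysis from −0.30 to 0.62.

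Of the 109 list results that passed, 0 passed with an estimated correlation and 77 with fry, and none of the 109 was lost without a filter. Their sign and call held in 99 with the covariate, 99 without the adipose and muscle arrays, 102 after quantile normalization, 108 after median centring, 106 with array weights, 106 with only the arrays compared, 103 with a replicate block, 103 of 108 with the mean of probe sets and 94 of 105 under the stricter filter. They held in 549 of 612 omissions of 1 array. Of 285 values of named genes 0 reversed, where a change of sign counts only if the value passed in the main or the altered fit. The call was lost in 61 with a replicate block, 43 with the covariate, 40 without the adipose and muscle arrays and 28 with only the arrays compared, and in 331 of 1828 values with 1 array left out. Signal over background sets which genes are seen at all: 13783 of 18193 passed the filter.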

Other observations

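Gene families were defined by patterns in their symbols, for cyclins and CDKs those of the A, B, D and E cyclins and of Cdk1, Cdk2, Cdk4 and Cdk6. They were chosen only after the results were seen, some because a member stood among the largest changes, so their p-values describe and do not test. Of 24 Hox genes 14 fell and 1 rose with the combination over both kinds of recipient (median −0.36, camera adjusted p = 7.19e-04, and 0.2991 with an estimated correlation), and 12 fell in each kind of recipient taken alone. Of 20 V-ATPase genes, which acidify lysosomes and melanosomes, 15 rose and 2 fell (median 0.42, adjusted p = 9.00e-04, and 0.2991 with an estimated correlation). Of 11 cyclin and CDK genes 7 fell and 2 rose (median −0.49, adjusted p = 0.0467, and 0.2991 with an estimated correlation). After median centring the 3 medians were −0.38, 0.39 and −0.52, and after quantile normalization −0.38, 0.46 and −0.46. Of 40 ribosomal protein genes 8 fell (adjusted p = 0.0585) and of 31 collagen genes 9 rose and 3 fell (adjusted p = 0.3239), and neither family passed. Between pmel-1 and control recipients, of 26 chemokine genes 7 rose and 1 fell (median 0.27, adjusted p = 6.54e-09, and 0.0464 with an estimated correlation).

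The hybridisation controls added to each array averaged 10.94 ± 0.22 (SD, n = 7) in the pmel-1 tumours given a drug and 10.49 ± 0.12 (SD, n = 6) in the others (two-sided exact permutation p = 0.0023). Replicate numbers did not pair the arrays: 1 of 13 arrays correlated best with an array of its own number once group means were taken out. Array weights ran from 0.54 (pmel-1 combination replicate 1) to 1.74 (pmel-1 combination replicate 3).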
